A study of Arabidopsis thaliana with 12 samples.

How the data were processed

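The series holds 12 RNA-seq libraries of Arabidopsis seedlings in 4 groups of 3, per the labels: dark wild type, wild type moved to white light for 6 h, and the dark-grown mutants det1-1 and pifq. Seeds were kept at 4 °C for 3 days, given 12 h of light and then grown for 4 days in the dark, per the labels' protocols. Total RNA was extracted with a Qiagen kit and sequenced from Illumina libraries, per the same protocols. TopHat, Cufflinks and the TAIR10 build are named in the submitters' processing notes. Their versions and settings, the handling of strand and of reads that map to several places, and the annotation were not given in the sources used here.

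The authors deposited 3 tables, each setting 1 group against dark wild type. Every table gives the authors' FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), with 1 value per gene and group, and a log2 ratio of the 2 values as the authors' program wrote it. The unit is not named in the headers and was taken from Cufflinks and from the values. Wherever both values are above 0 and a comparison was made, the largest difference of the deposited log2 ratio from that of the deposited FPKM values was 0.0047 for light, 0.0015 for det1-1 and 0.0074 for pifq; the ratio is 0 where the program made none. The tables do not hold values per library, read counts, p-values or a measure of spread. The depth is therefore unknown, no SD or n accompanies any value, and low FPKM values are less certain to a degree that cannot be stated. The text calls the columns the authors' values.

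A test per gene had been planned with the authors' q-values or with replicate values, and exact tests on gene lists and tests of differences between mutants with them. None could be run on these tables, so group values are described, as had been set out for that case. Log2 folds were computed from the FPKM values with no pseudocount. A gene was analysed where it had a single entry in the table, the authors' program had compared it, both groups were above 0, and the higher group reached 1 FPKM. Each table was also scaled so that its dark wild type matched that of the light table (factors 0.927 for the det1-1 table and 0.971 for the pifq table, from the median ratio). A gene was kept where its dark wild type values then agreed within 1.5-fold over the tables that hold it. This left 14810, 14844 and 15014 genes of 17039, 16642 and 17253 for light, det1-1 and pifq, and 1313 of those in the pifq table were in that table alone and had no such check. Entries without a gene name (291, 291 and 231) stayed out and held 10.8%, 15.3% and 10.5% of the dark wild type FPKM sum, and 7.25%, 1.79% and 1.05% of that of the group compared with it. Genes with several entries (533, 533 and 523) were left out, as were genes at 0 in 1 group; 84, 63 and 131 of the latter reached 5 FPKM in the other group, and since multi-copy genes of photosynthesis are among those listed at 0, an exact 0 can be a failed estimate.

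A gene is called higher or lower at 2-fold or more. This stands in for a test and says nothing of the spread between libraries. The gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The use of 2-fold as the call, the minimum of 1 FPKM as the setting reported, the 1.5-fold tolerance, the treatment of genes with several entries, 16 families taken by product name, and a further seed list of 17 genes were chosen after the tables had been seen.

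The rule names, per comparison, DET1, PIF1, PIF3, PIF4, PIF5, HY5 and CHS, the 4 genes with the largest log2 fold each way among those with at least 5 FPKM in the higher group, and up to 3 members of each list past 2-fold with the largest absolute log2 fold. For differences between det1-1 and pifq it names the 4 largest each way, among genes with at least 5 FPKM in a group. ELIP1 and BGLU24 as the genes furthest up in light against the mutants, RAB18 and ABI5 in det1-1, PIF8, LFY, QQS and OLEO3 were chosen after their values were seen. The lists hold 367 genes: light-harvesting antenna, nuclear photosystem subunits, Calvin cycle, chlorophyll, carotenoid, flavonoid, photomorphogenesis regulators, PIF-activated growth and shade genes, auxin, cell wall, gibberellin, brassinosteroid, ethylene, circadian clock, plastid transcription, seed maturation and storage, heat stress, defence and jasmonate, cell division, stomatal lineage, root and PIF family. Plastid and mitochondrial genes were counted apart by identifier. Of the members, 286, 285 and 278 were analysed in light, det1-1 and pifq. A list's median log2 fold is given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression.

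For comparisons between tables, Pearson and Spearman correlations, covariances and shared calls were computed over the 13820 genes compared in all 3. Chance values come from 100 draws of unchanged groups that share a control, with the whole central spread of the observed folds per expression bin taken as noise. The control's part of that noise was assumed, since it could not be measured. Under that assumption the chance covariances and counts are upper estimates. The simulated r does not grow with the noise and is set by the assumed part. The overlap of independent lists is the product of both call counts over the number of genes. Gene positions, products and overlaps are from the TAIR10.1 annotation used here, and the share of each gene's exonic 32-base stretches found elsewhere in the genome was counted from its sequence. Among the named genes, LHCB1.2, SAUR24, CYCB1;2, SAUR22, PIF1, LDOX, VSP1, 2S2, XTH19 and AT4G04408 have over 5% such stretches and are uncertain. BBX25, BCH2, CAO, CASP1, CHLI1, CHS, CPD, CYCD3;1, EXPA18, FKF1, GASA6, GH3.9, GRF7, HCEF1, HSP17.4, LCYE, LHCA5, LHCB2.3, LNK1, LUT5, PGK1, PIF1, PIF7, PORB, PSAH2, PSAN, PSY, PTAC12, RAB18, RCA, SNRK2.5, TRXZ, XTH15, AT4G04408, AT5G04120 and AT5G55570 overlap another annotated gene, from which reads cannot be told apart without strand.

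The steps were tested on simulated data before use, with 200 changed genes per comparison and noise of 0.3 (SD, log2) on each group value. At a log2 fold of 3 either way, 100% were called in each comparison, over 15626, 15641 and 15638 genes for light, det1-1 and pifq. At -1.5 and 1.5 they were 87.5% and 86% for light, 92% and 98% for det1-1, and 84% and 94% for pifq. Of unchanged genes, 1.78%, 2.08% and 1.88% were called. The noise was chosen for this check and not measured from the libraries, so these shares are not error rates of the calls reported here. Alternatives changed the pseudocount (0.1, 1 and 5 FPKM), the minimum level, the fold, the tolerance between tables, the scaling, the treatment of genes with several entries, the inclusion of organelle genes and of genes with repeated sequence. Computation used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.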

Results

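RNA sequencing was used to measure transcript levels in whole Arabidopsis thaliana seedlings. The seedlings had been grown in darkness for 4 days. There were 12 libraries in 4 groups of 3. Wild type (Columbia) was sampled in the dark and after a move to white light for 6 h. The mutants det1-1 and pifq were sampled in the dark. DET1 is a nuclear repressor of photomorphogenesis, the development that seedlings normally begin only in light. The PIFs are basic helix-loop-helix factors that promote dark growth and are removed when phytochromes sense light, and pifq carries mutations in PIF1, PIF3, PIF4 and PIF5. The design sets each of 3 conditions against dark wild type, and asks how far loss of DET1 resembles loss of the PIFs or exposure to light.

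The values are the authors' FPKM, a single value per gene and group. They carry no spread between the 3 libraries, no read count and no p-value, so the depth is unknown and no difference reported here has a replicate check. Of 218 folds of genes named by rule, 13 that had reached 2-fold were under it with 1 FPKM added to both groups: ABI5, ACS6, BASL, CRC, ERF1 and VSP2 in light, BAS1, HSP22 and PR1 in det1-1, and ATMG00130, CYCB1;1, CYCB1;2 and ERF1 in pifq. With 5 FPKM added, 49 fell under it. Genes are called higher or lower where they differed from dark wild type by at least 2-fold. A gene well under 1 FPKM in dark wild type could be analysed only if it was higher in the other group. Counts and medians of lists with such genes therefore lean upward. The genes analysed numbered 14810 for light, 14844 for det1-1 and 15014 for pifq, and their median log2 fold was 0.02, -0.03 and 0.01. Where a pair of levels is written from one value to another, the dark wild type comes first. Each list's median log2 fold is given with its percentile among 10000 random lists of the same size matched on expression, where 0 and 100 mean that no random list was lower or higher; this describes these values and is not a test. The 3 tables were normalized separately, so a level in one is not strictly comparable with a level in another. The dark wild type appears in all of them: 96.1% of 16767 genes had values within 1.5-fold in the light and det1-1 tables after scaling, 88.6% of 15939 in the light and pifq tables, and 85.3% of 15922 in the det1-1 and pifq tables.

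The targeted genes were read first. PIF3 (AT1G09530, chromosome 1, 3075768 to 3079654, plus strand of TAIR10.1) was 30.2 FPKM in dark wild type and 0.802 FPKM in pifq, a log2 fold of -5.24. PIF5 (AT3G59060, chromosome 3, 21827905 to 21830837, minus strand) was 9.44 and 1.39 FPKM, a log2 fold of -2.77. PIF1 (AT2G20180, chromosome 2, 8704024 to 8707009, minus strand) and PIF4 (AT2G43010, chromosome 2, 17886101 to 17889087, plus strand) were not lower in pifq, at 23.7 against 19.2 FPKM and 20.9 against 20.5 FPKM. These values are over the whole annotated gene, and the labels do not say where the lesions lie, so a transcript that is still made from a disrupted gene is counted here. The dark wild type value of PIF4 was 11.2 FPKM in the light table and 20.5 FPKM in the pifq table, and PIF4 was left out of the analysed set. DET1 (AT4G10180, chromosome 4, 6346411 to 6349314, plus strand) was 15.1 FPKM in dark wild type and 16.7 FPKM in det1-1. Its level does not test the label, since det1-1 is known as a point allele, which need not lower a transcript. In det1-1, PIF3 was 14.6 against 28.1 FPKM, PIF1 16.1 against 15.8 FPKM, PIF4 33.2 against 10.4 FPKM and PIF5 31.5 against 8.96 FPKM. In light, DET1 was 25.6 against 16.3 FPKM, PIF1 21.5 against 19.7 FPKM, PIF3 30.7 against 30.3 FPKM (with no comparison made by the authors' program), PIF4 8.03 against 11.2 FPKM and PIF5 12.0 against 9.67 FPKM. In pifq, DET1 was 18.7 against 15.6 FPKM.

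Exposure to white light for 6 h came with higher transcripts for photosynthesis and pigments and lower transcripts for auxin response and for PIF-activated genes. CHS, which makes the first committed step of flavonoid synthesis, was 4.88 FPKM in the dark and 1809 FPKM in light, 371-fold higher. ELIP1, a chlorophyll-binding protein that protects greening plastids, was 395-fold higher, from 3.48 to 1373 FPKM. HY5, the bZIP factor that promotes photomorphogenesis, was 3.88-fold higher, from 29.5 to 115 FPKM. In the other direction, IAA6, an auxin-inducible repressor of auxin response, was 46.4 FPKM in the dark and 0.311 FPKM in light, and 16 of 19 PIF-activated genes were at least 2-fold lower.

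In all, 1832 genes (12.4%) were at least 2-fold higher in light and 1494 (10.1%) at least 2-fold lower. With 5 FPKM added to both groups, 918 were higher and 694 lower. Among genes with at least 5 FPKM in the higher group, the largest log2 folds were those of DFR (11.99) and LDOX (9.01), which make anthocyanin precursors, of the UDP-glycosyltransferase gene AT2G22590 (9.00) and of ELIP1 (8.62). DFR, LDOX and AT2G22590 were 0.0111, 0.106 and 0.0558 FPKM in the dark, so their folds are set by values close to 0. The lowest at that level were the SAUR-like genes AT4G13790 (-8.05) and AT4G09530 (-7.98), RTFL21 (-7.67), which encodes a small ROTUNDIFOLIA-like peptide, and SAUR68 (-7.41), of the small auxin-induced family tied to cell elongation. All of these lower genes were at most 0.490 FPKM in light. With 1 FPKM added to both groups the log2 folds were DFR 5.51, LDOX 5.65, AT2G22590 4.81, ELIP1 8.26, AT4G13790 -4.81, AT4G09530 -4.54, RTFL21 -6.08 and SAUR68 -3.09.

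Of 13 antenna genes, 10 were higher in light and 0 lower, with a median log2 fold of 2.12 (percentile 100). LHCA1 went from 45.4 to 756 FPKM, LHCB2.3 from 18.4 to 202 FPKM and LHCA5 from 8.93 to 71.5 FPKM. Nuclear photosystem subunits were higher in 18 of 21 (median 2.08, percentile 100), among them PSAH2 (31.1 to 430.4 FPKM), PSAK (75.7 to 664 FPKM) and PSAO (79.0 to 602 FPKM). In the Calvin cycle, 7 of 12 genes were higher (median 1.17, percentile 99.97), including RCA, which activates Rubisco, from 137 to 1141 FPKM, FBA1 from 30.7 to 243 FPKM and GAPA2 from 41.1 to 244 FPKM. Chlorophyll synthesis genes were higher in 11 and lower in 2 of 21 (median 1.25, percentile 100). The magnesium chelatase subunits CHLH (21.5 to 172 FPKM) and CHLI1 (18.9 to 113 FPKM) were higher. PORA, the protochlorophyllide reductase of etiolated seedlings, was lower, from 178 to 3.08 FPKM. Carotenoid genes were higher in 8 of 12 (median 1.26, percentile 100), with LUT5 from 1.57 to 19.6, LCYE from 5.76 to 21.1 and PSY, the entry enzyme, from 13.8 to 71.4 FPKM. The plastid transcription machinery was higher in 7 of 11 (median 1.33, percentile 100), led by the sigma factor SIG5 from 1.485 to 66.4 FPKM, then FLN1 (log2 2.29) and SIG1 (1.97).

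All 17 analysed flavonoid genes were at least 2-fold higher (median 6.48, percentile 100, and 4.098 with 1 FPKM added to both groups), with DFR, LDOX and CHS at the top. Members as low in the dark as DFR, LDOX and GSTF12 (0.0111, 0.106 and 0.155 FPKM) could be analysed only if at least 2-fold higher. The minimum level therefore fixed part of this count. The list of photomorphogenesis regulators also holds photoreceptors and the ELIP genes of chlorophyll-binding proteins. In it, 13 of 22 were higher and 4 lower (median 1.65, percentile 100). ELIP1, ELIP2 (5.45 to 854 FPKM) and the B-box factor BBX25 (0.408 to 58.6 FPKM) were among the higher. PIF-activated genes had a median of -2.30 (percentile 0), with the kinase gene SNRK2.5 from 63.9 to 1.55, the wall-modifying XTH15 from 1097 to 34.2 and PAR1 from 43.8 to 3.09 FPKM. Auxin genes were lower in 17 and higher in 1 of 24 (median -2.46, percentile 0; -1.20 without genes of repeated sequence), led by SAUR68, IAA6 and SAUR22 (48.1 to 1.65 FPKM). Cell wall genes were lower in 9 and higher in 4 of 17 (median -1.23, percentile 0), with XTH5 from 26.7 to 1.51, EXPA11 from 160.0 to 20.6 and XTH19 from 183 to 25.7 FPKM. That median was 0.026 when genes with sequence repeated elsewhere in the genome were left out, and -0.60 without the tolerance between tables. Gibberellin genes were lower in 6 and higher in 2 of 16 (median -0.91, percentile 0). GA2OX1, which inactivates the hormone, was higher (0.105 to 17.7 FPKM), and GA20OX1 (8.38 to 1.18 FPKM) and GA3OX1 (32.3 to 6.86 FPKM), which make it, were lower.

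Brassinosteroid genes had a median of -0.94 (1 higher and 3 lower of 9, percentile 0.13), with BAS1 (log2 -1.77) and CPD (-1.67) lower and BR6OX2 (1.16) higher. Ethylene genes had a median of -0.60 (4 lower and 0 higher of 13, percentile 0.875). HLS1, needed for the apical hook, was 10.99 FPKM in the dark and 0.887 FPKM in light, and ERF1 (log2 -2.05) and ACS6 (-1.06) were also lower. Clock genes had a median of 0.16 (4 higher and 1 lower of 13, percentile 76.4), but ELF4 was 28.8-fold higher, and LNK1 (log2 2.69) and FKF1 (2.67) were higher too. All 5 analysed heat stress genes were higher (median 1.93, percentile 99.93), among them HSFA2 (log2 2.56), HSP17.6II (2.03) and HSP17.4 (1.93). Stomatal lineage genes were higher in 3 of 4 (median 3.05, percentile 99.97, and 1.402 with 1 FPKM added to both groups). EPF2 went from 0.252 to 4.94 and SPCH from 0.390 to 4.38 FPKM, and BASL had a log2 fold of 2.62, which was 0.85 with 1 FPKM added to both groups. EPF2, SPCH and BASL were so low in the dark that they could be analysed only if higher in light, so the minimum level fixed the direction of these calls. The same dark wild type libraries gave BASL 0.173 FPKM in the comparison with det1-1. Seed genes were lower in 3 and higher in 0 of 10 (median -0.52, percentile 3.23): EM1 (log2 -1.81), ABI5 (-1.15) and CRC (-1.12). None of 12 cell division genes (median -0.22, percentile 10.3) or 8 root genes (median 0.41, percentile 90.9) differed by 2-fold. Defence and jasmonate genes had 3 analysed members (median 0.72, percentile 89.0), of which VSP2 was higher (log2 1.04). Of 4 PIF family genes, PIF7 was higher, from 0.456 to 3.93 FPKM (list median 0.22, percentile 69.5). Plastid-encoded genes had 5 analysed members, 2 lower (median -0.64, percentile 4.50; -1.18 without the tolerance between tables), ATCG00040 among them from 35.9 to 13.5 FPKM. Mitochondrial genes had 4, 1 lower (median -0.64, percentile 7.93).

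**Figure D1:**
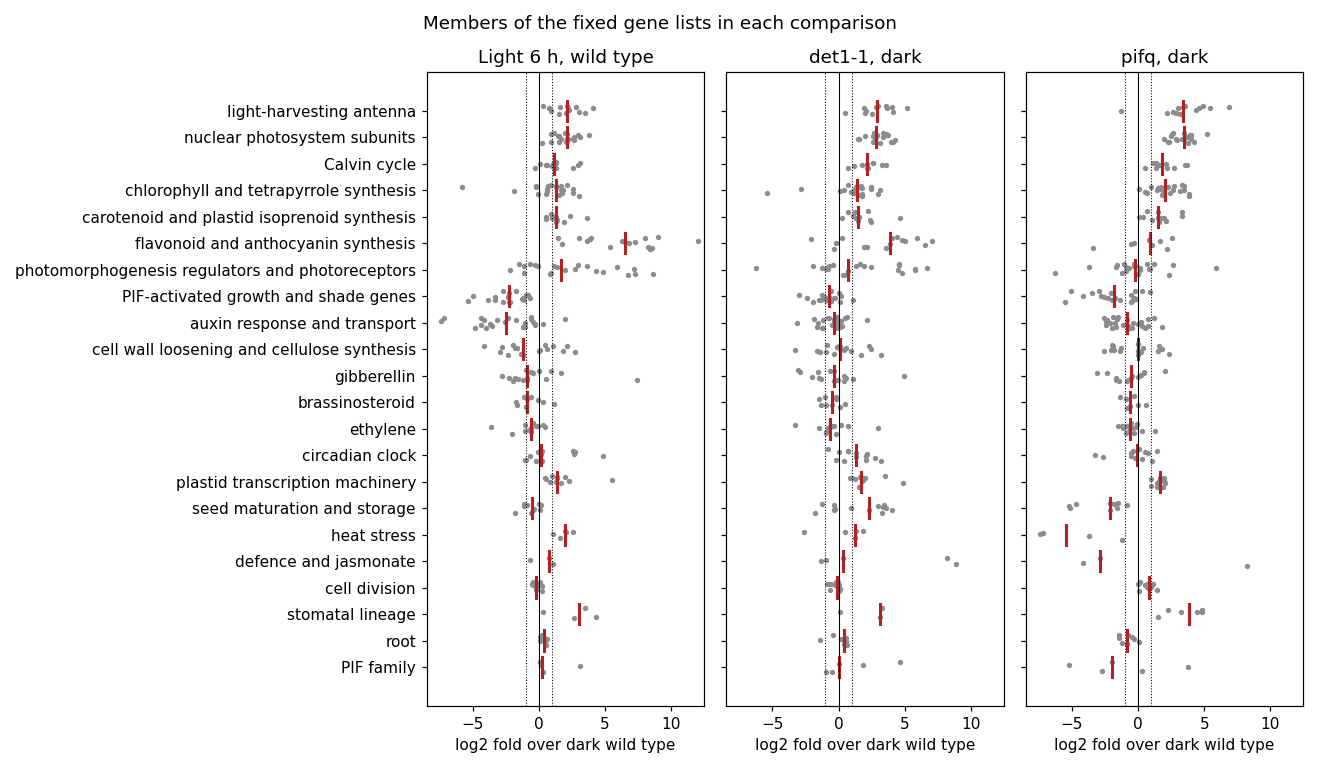
Log2 fold over dark wild type (horizontal axis) of each analysed member of the gene lists (vertical axis), in separate panels for light, det1-1 and pifq. Each point is a gene, the red bar is the list's median and dotted lines mark 2-fold. Flavonoid genes have medians of 6.48 in light, 3.86 in det1-1 and 0.91 in pifq, and photosystem genes of 2.08, 2.84 and 3.47.

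In the dark, det1-1 seedlings had high transcripts for photosynthesis, and intermediate ones for flavonoids. LHCA1, an antenna protein of photosystem I, was 36.2-fold higher than in dark wild type, from 42.1 to 1523 FPKM. CHS was 90.7-fold higher, from 4.53 to 411 FPKM. HY5 was 27.4 FPKM in wild type and 35.0 FPKM in det1-1, under 2-fold. PORA was 161 FPKM in wild type and 3.72 FPKM in the mutant. The seed storage cruciferin CRC was higher, from 3.79 to 44.3 FPKM, as was the albumin 2S2, from 1.12 to 18.0 FPKM.

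In all, 2562 genes (17.3%) were higher in det1-1 and 1441 (9.71%) lower. With 5 FPKM added to both groups, 1333 were higher and 543 lower, and without the minimum of 1 FPKM 2198 were lower. Among genes with at least 5 FPKM in the higher group, the largest log2 folds were those of AT5G55570 (10.20), CIPK20 (9.04), a protein kinase of the calcium sensor network, the RING finger gene AT3G11110 (9.03) and LOX2 (8.89), a lipoxygenase of jasmonate synthesis. All of these were under 0.1 FPKM in the dark wild type, which sets the size of their folds, and AT5G55570 overlaps AT5G55580. The lowest at that level were the F-box gene AT1G20790 (-6.54), the B-box factor BBX23 (-6.22), GRF7 (-6.07), a growth-regulating factor, and HEC2 (-6.04), a basic helix-loop-helix factor, which was 42.6 FPKM in wild type and 0.647 FPKM in det1-1. With 1 FPKM added to both groups the log2 folds were AT5G55570 3.70, CIPK20 5.56, AT3G11110 4.35, LOX2 3.80, AT1G20790 -3.59, BBX23 -3.39, GRF7 -4.31 and HEC2 -4.73.

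Antenna genes were higher in 11 of 12 (median 2.89, percentile 100), with LHCA5 from 8.27 to 146 and LHCB1.2 from 28.8 to 464 FPKM. LHCB1.2 is uncertain, since 24.0% of its 32-base stretches occur elsewhere in the genome. All 20 photosystem genes were higher (median 2.84, percentile 100), including PSAO (73.2 to 1389 FPKM), PSAN (77.6 to 1318 FPKM) and PSBO2 (27.5 to 437 FPKM). The Calvin cycle was higher in 9 of 10 (median 2.17, percentile 99.95), with GAPA2 from 38.1 to 451 and PGK1 from 105 to 648 FPKM and FBA1 at a log2 fold of 3.29. Chlorophyll genes were higher in 15 and lower in 2 of 21 (median 1.39, percentile 100), with CHLH from 19.97 to 175 and CHLI1 from 17.39 to 136 FPKM. Carotenoid genes were higher in 10 of 12 (median 1.503, percentile 100), with LUT5 from 1.46 to 35.5 and ZEP from 20.9 to 108 FPKM and BCH2 at a log2 fold of 2.45. Plastid transcription genes were higher in 10 of 11 (median 1.69, percentile 99.98), with SIG5 from 1.38 to 39.8, FLN1 from 2.95 to 33.7 FPKM and PTAC12 at a log2 fold of 2.02. Plastid-encoded genes had 4 analysed members (median -0.53, percentile 8.12), with ATCG01020 higher (log2 1.01) and ATCG00040 lower (-1.49). Mitochondrial genes had 3, of which 2 were lower (median -1.31, percentile 0.545; -0.20 without the minimum of 1 FPKM), ATMG00060 among them (log2 -1.55).

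Flavonoid genes were higher in 11 and lower in 1 of 15 (median 3.86, percentile 100, and 1.08 with 1 FPKM added to both groups). DFR (0.0103 to 1.38 FPKM) and the bHLH regulator TT8 (0.0193 to 1.16 FPKM) had large folds on low levels. DFR, TT8, LDOX, 5MAT, GSTF12 and MYB12 were so low in wild type that they could be analysed only if at least 2-fold higher. Photomorphogenesis regulators were higher in 11 and lower in 3 of 23 (median 0.68, percentile 99.86), with the B-box factors BBX25 from 0.342 to 36.0 and BBX30 from 0.761 to 42.5 FPKM. PIF-activated genes were lower in 7 and higher in 1 of 19 (median -0.71, percentile 0.02), including SNRK2.5 (59.1 to 7.30 FPKM), XTH15 (1017 to 189 FPKM) and ARF18 (log2 -1.97). Auxin genes were lower in 7 and higher in 1 of 24 (median -0.35, percentile 2.11), with IAA6 from 43.0 to 4.83, IAA17 from 315 to 88.7 and SAUR14 from 14.8 to 64.8 FPKM. Cell wall genes were split, 4 higher and 3 lower of 17 (median 0.078, percentile 54.9): XTH22 (26.4 to 245 FPKM) and EXPA1 (46.1 to 254 FPKM) were higher and XTH5 (24.8 to 2.52 FPKM) was lower. Gibberellin genes were lower in 6 and higher in 2 of 16 (median -0.32, percentile 7.67), with GASA4 from 3642 to 440.4, GA3OX1 from 30.0 to 4.03 FPKM and GA2OX1 at a log2 fold of 4.92. Brassinosteroid genes were lower in 3 of 9 (median -0.46, percentile 5.69): BR6OX1 (log2 -1.49), DWF4 (-1.37) and BAS1 (-1.05). Ethylene genes were lower in 2 and higher in 1 of 13 (median -0.65, percentile 0.445), with HLS1 from 10.2 to 1.03 and ACO4, which makes ethylene, from 92.5 to 721 FPKM, and ACS6 at a log2 fold of -1.46.

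Clock genes were higher in 7 of 13 (median 1.33, percentile 99.97), among them the blue-light receptor FKF1 (1.402 to 13.0 FPKM), PRR5 (3.41 to 23.4 FPKM) and LNK1 (log2 2.18). Seed genes were higher in 7 and lower in 2 of 13 (median 2.304, percentile 100, bootstrap 95% interval -0.32 to 3.33; 1.31 with 1 FPKM added to both groups, and 0.97 without genes of repeated sequence), with the cruciferin CRB from 0.178 to 1.92 FPKM, and RAB18 (log2 -1.80) and ABI5 (-1.29) lower. Heat stress genes were higher in 3 and lower in 1 of 5 (median 1.26, percentile 95.6; 0.62 with 1 FPKM added to both groups): HSP17.6II (log2 1.86), HSP18.2 (1.31) and HSP22 (-2.60). Defence and jasmonate genes were higher in 2 and lower in 1 of 5 (median 0.35, percentile 76.95; 4.26 without genes of repeated sequence), with LOX2 from 0.0280 to 13.3 and PR5 from 0.0181 to 5.24 FPKM, and PR1 at a log2 fold of -1.29. Stomatal genes were higher in 2 of 3 (median 3.11, percentile 99.3, and 1.29 with 1 FPKM added to both groups), SPCH at a log2 fold of 3.25 and EPF2 at 3.11. SPCH and EPF2 were 0.362 and 0.233 FPKM in wild type and could be analysed only if higher, while MUTE and BASL stayed under 1 FPKM. Among 7 root genes, CASP1 of the Casparian strip was lower, from 349 to 133 FPKM (median 0.40, percentile 85.5). None of 12 cell division genes differed by 2-fold (median -0.15, percentile 35.9). Of 5 PIF family genes, PIF7 (0.422 to 10.5 FPKM) and PIF5 were higher (median 0.026, percentile 59.3; 1.67 without the tolerance between tables).

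In dark pifq seedlings, photosynthesis transcripts were high, and 12 of 20 PIF-activated genes and 9 of 10 seed genes were lower. Of 23 flavonoid genes, only 8 were analysed, of which 4 were higher. PSAH2, a photosystem I subunit, was 37.8-fold higher, from 29.6 to 1119 FPKM. CHS was 4.76 FPKM in wild type and 8.26 FPKM in pifq. PIL1 and HFR1, bHLH genes that PIFs activate in shade, were 24.3 and 88.0 FPKM in wild type and 0.516 and 2.56 FPKM in pifq. HY5 was 28.8 FPKM in wild type and 12.4 FPKM in pifq, a log2 fold of -1.21, which was -0.95 with 5 FPKM added to both groups. RAB18, a dehydrin of dry seeds, was 105 and 2.96 FPKM.

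In all, 1937 genes (12.9%) were higher in pifq and 1975 (13.2%) lower. With 5 FPKM added to both groups, 792 were higher and 955 lower. Among genes with at least 5 FPKM in the higher group, the largest log2 folds were those of GH3.9 (8.84), LOX2 (8.23), AT5G48490 (8.04), of the lipid-transfer type, and AT1G10657 (7.72). AT5G48490 was 2.34 FPKM in wild type and 618 FPKM in pifq, while GH3.9, LOX2 and AT1G10657 were at 0.0160, 0.0294 and 0.113 FPKM in wild type, which sets the size of their folds. The lowest at that level were AT5G04120 (-9.25), of the phosphoglycerate mutase family, which overlaps AT5G04130, the lipid transfer protein gene LTP4 (-8.62), AT3G21805 (-7.32), from 909 to 5.70 FPKM, and AT3G62990 (-6.35). With 1 FPKM added to both groups the log2 folds were GH3.9 3.03, LOX2 3.25, AT5G48490 7.53, AT1G10657 4.47, AT5G04120 -5.56, LTP4 -5.93, AT3G21805 -7.09 and AT3G62990 -4.32.

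Antenna genes were higher in 12 and lower in 1 of 13 (median 3.36, percentile 100), with LHCB1.2, uncertain for its repeated sequence, from 44.5 to 5127, LHCA1 from 31.6 to 1387 and LHCB2.3 from 17.9 to 526 FPKM. All 20 photosystem genes were higher (median 3.47, percentile 100), including PSAO (76.8 to 1428 FPKM) and PSAK (73.4 to 1182 FPKM). Calvin cycle genes were higher in 9 of 10 (median 1.81, percentile 99.99), with GAPA2 from 39.9 to 515, RCA from 133 to 1509 and HCEF1 from 26.9 to 177 FPKM. Chlorophyll genes were higher in 16 of 20 (median 2.06, percentile 100), with CHLI1 from 18.22 to 267, CHLH from 20.9 to 302 and CAO, which makes chlorophyll b, from 7.99 to 90.1 FPKM. Carotenoid genes were higher in 9 of 12 (median 1.53, percentile 100), with PSY from 13.1 to 128 FPKM, LUT5 at a log2 fold of 3.28 and LCYE at 2.099. Plastid transcription genes were higher in 11 of 13 (median 1.63, percentile 100), led by FLN1 (log2 2.03), FLN2 (1.98) and TRXZ (1.93). Plastid-encoded genes had only 2 analysed members (median -0.41), and mitochondrial genes had 12, of which 8 were lower (median -1.29, percentile 0.01), such as ATMG00700 (3.42 to 0.273 FPKM) and ATMG01370 (4118 to 1106 FPKM). ATMG00700, ATMG01370 and TRXZ were listed only for the pifq comparison, so their dark wild type values had no check. In det1-1, mitochondrial genes such as ATMG00030 and ATMG01360 were left out because their dark wild type was not repeated.

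Flavonoid genes had 8 analysed members of 23, 4 higher and 1 lower (median 0.91, percentile 98.2). Among the 15 left out, DFR, 5MAT, GSTF12, MYB12 and TT8 stayed under 1 FPKM in both groups. Of the higher genes, 4CL3 and MYB111 reached 1 FPKM only in pifq, so the count does not describe the whole pathway. UGT78D1 was higher (2.53 to 14.7 FPKM), as was 4CL3 (log2 2.15), and the MYB regulator PAP1 was lower (1.71 to 0.159 FPKM). Genes of the photomorphogenesis list were higher in 4 and lower in 6 of 22 (median -0.27, percentile 7.69). The GATA factor CGA1 was higher (0.0992 to 5.87 FPKM), and BBX23 (11.6 to 0.144 FPKM) and the chlorophyll-binding ELIP1 (3.39 to 0.256 FPKM) were lower. PIF-activated genes were lower in 12 of 20 (median -1.85, percentile 0), with XTH15 from 1064 to 59.0 FPKM after PIL1 and HFR1. Auxin genes were lower in 12 and higher in 2 of 26 (median -0.81, percentile 0): SAUR24 (84.9 to 13.9 FPKM), which has 24.7% repeated sequence and is uncertain, IAA6 (45.2 to 8.31 FPKM) and SAUR68 (log2 -2.43). Cell wall genes were lower in 7 and higher in 4 of 17 (median -0.030, percentile 69.9), with XTH5 at a log2 fold of -2.60, XTH9 from 9.47 to 47.2 and XTH24 from 855 to 208 FPKM. Gibberellin genes were lower in 5 and higher in 1 of 15 (median -0.57, percentile 1.67), with GA3OX1 from 31.3 to 5.97, GASA6 from 141 to 578 FPKM and GA2OX8 at a log2 fold of -3.09. Of 7 brassinosteroid genes, BR6OX2 was lower (log2 -1.39; list median -0.65, percentile 3.75). Ethylene genes were lower in 3 and higher in 1 of 14 (median -0.61, percentile 2.38): ERF1 (log2 -1.53), ACS6 (-1.25) and ACO4 (1.24).

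Clock genes were divided, 2 higher and 2 lower of 12 (median -0.086, percentile 41.8), with PRR7 from 10.9 to 1.11, LNK1 from 4.47 to 0.722 and LHY from 14.0 to 38.2 FPKM. PRR7, like CRA1 and CYCB1;1 below, was listed only for the pifq comparison, so its dark wild type had no check. Seed genes were lower in 9 of 10 (median -2.13, percentile 0; -1.43 with 1 FPKM added to both groups), among them the cruciferins CRC (4.199 to 0.113 FPKM) and CRA1 (13.5 to 0.524 FPKM). All 4 analysed heat stress genes were lower (median -5.47, percentile 0; -1.39 with 1 FPKM added to both groups and -1.24 without the minimum of 1 FPKM), with HSP17.4 from 3.42 to 0.02, HSP22 from 1.51 to 0.0101 and HSP17.6II from 2.23 to 0.171 FPKM. Over 37 genes with names of heat shock proteins, a family chosen after the tables had been seen, 6 were higher and 8 lower (median 0.074, percentile 65.3). Defence and jasmonate genes had 3 members, LOX2 higher (0.0294 to 8.82 FPKM) and the vegetative storage genes VSP1 (17.3 to 0.971 FPKM) and VSP2 (log2 -2.85) lower (median -2.85, percentile 0.08; -1.78 with 1 FPKM added to both groups, -1.06 without the tolerance between tables and -0.59 without the minimum of 1 FPKM). Cell division genes were higher in 3 of 13 (median 0.80, percentile 99.8): CYCD3;1 (8.29 to 22.4 FPKM), CYCB1;1 (log2 1.11) and CYCB1;2 (1.05). All 6 analysed stomatal lineage genes were higher (median 3.84, percentile 100, and 1.84 with 1 FPKM added to both groups). SPCH, which starts the lineage, went from 0.379 to 10.9, EPF2 from 0.242 to 6.74 and BASL from 0.181 to 3.91 FPKM. SPCH, EPF2, BASL and MUTE were so low in wild type that they could be analysed only if higher, so the minimum level fixed the direction of their calls. For MUTE, the same dark wild type libraries gave 0.137 FPKM in the comparison with det1-1. Root genes were lower in 3 of 8 (median -0.82, percentile 1.13): PRP3 (63.7 to 23.0 FPKM), CASP1 (342 to 128 FPKM) and EXPA18 (log2 -1.20). Among 5 PIF family genes, 3 were lower and PIF7 was higher (0.330 to 4.61 FPKM; median -1.98, percentile 0.03). With PIF4 and PIF8 included, whose dark wild type values were not repeated between tables, that median was 0.029.

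Set against each other, det1-1 and pifq both had high photosynthesis transcripts, and differed in flavonoid and seed transcripts and in those of the light-dependent chlorophyll enzymes of etiolated seedlings. PORA was 3.72 FPKM in det1-1 and 181 FPKM in pifq, against 161 and 173 FPKM in the dark wild type of the respective tables. Its relative PORB was 29.7 and 1129 FPKM, against 214 and 235 FPKM. BBX30, a small B-box protein, was 42.5 FPKM in det1-1 and 0.0349 FPKM in pifq. Of 15 flavonoid genes, 10 were at least 2-fold further up in det1-1 than in pifq and 0 further down, with a median log2 difference of 2.65 (percentile 100). With 1 FPKM added to each group, 7 were further up and 0 further down, and the median difference was 0.85, under 2-fold. DFR, 5MAT, GSTF12, MYB12, TT8 and UGT79B1 were under 1 FPKM in pifq and its dark wild type. They entered only through det1-1 or light, so the count leans towards genes high there. PAP1 counts as further up in det1-1, though it was lower in both mutants (log2 -2.10 in det1-1 and -3.43 in pifq).

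A set of 13820 genes was compared in all 3 tables and reached 1 FPKM in at least 1 group. Over this set, the log2 folds of det1-1 and pifq had Pearson r 0.59 and Spearman rho 0.59 across genes, which are not independent replicates. Because every comparison uses the same dark wild type, unchanged groups simulated against a shared control were drawn 100 times, and gave r 0.38. The simulated r is set by the part of the noise assumed to lie in the control. An observed r above or below it therefore decides nothing about likeness. The covariance was 0.83 against 0.26 simulated. Genes higher in both numbered 1113 (286 for independent lists, 401 simulated), and genes lower in both 785 (174 and 402). Opposite calls numbered 115 (467 and 95.9). For light and det1-1, r was 0.62 and rho 0.56 (simulated r 0.43), the covariance 0.86 (0.26), 1058 genes were higher in both (275 for independent lists, 360 simulated), 552 lower in both (132 and 357) and 81 opposite (387 and 43.0). For light and pifq, r was 0.42 and rho 0.39 (simulated r 0.44), the covariance 0.55 (0.25), 728 genes were higher in both (204 and 354), 586 lower in both (179 and 353) and 206 opposite (385 and 46.9). In all 3 comparisons 663 genes were higher (162 simulated) and 370 lower (159). With 5 FPKM added to both groups, genes higher in both and lower in both numbered 498 and 347 for det1-1 and pifq. They numbered 472 and 236 for light and det1-1, and 302 and 283 for light and pifq. The controls have a single value per table and cannot be split.

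Per gene, 1804 were at least 2-fold further up in det1-1 than in pifq and 927 further down (457 with 1 FPKM added to each group), where unchanged groups gave 1711 and 1719. With 5 FPKM added, 836 were further up and 160 further down, and without a minimum level 1496 were further down. Among genes with at least 5 FPKM in a group, the largest differences in log2 fold were those of CIPK20 (11.16), BBX30 (10.32), AT3G44450 (9.75) and AT5G55570 (9.26), all with a group under 0.1 FPKM. In the other direction they were those of PORA (-5.50), PORB (-5.11), AT5G48490 (-4.92) and AT4G04408 (-4.30). PORB and AT4G04408 overlap other genes, and 8.04% of the 32-base stretches of AT4G04408 are repeated elsewhere, so both are uncertain. Seed genes were further up in det1-1 in 10 of 12 (median difference 4.76, percentile 100; 2.57 with 1 FPKM added to each group), heat stress genes in 4 of 5 (4.62, percentile 100; 1.78 with 1 FPKM added to each group), and PIF-activated genes in 10 of 19 (1.07, percentile 100). Root genes were further up in det1-1 in 4 of 7 (1.05, percentile 99.4) and defence and jasmonate genes in 3 of 4 (3.19, percentile 99.97; 2.19 with 1 FPKM added to each group). Antenna genes (-0.84), photosystem genes (-0.45), chlorophyll genes (-0.74) and cell division genes (-0.93) had median differences at percentile 0, and stomatal genes were further down in all 5 (-1.59, or -1.29 with 1 FPKM added to each group). Of these 5, MUTE and BASL were under 1 FPKM in det1-1 and in its dark wild type, and entered only through light or pifq. Calvin cycle (0.065), carotenoid (0.16) and plastid transcription genes (0.14) had median differences close to 0.

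Light and det1-1 differed by at least 2-fold in 1181 genes further up and 1748 further down in light, where unchanged groups gave 1455 and 1453. Light and pifq differed in 1960 and 1702 (1132 with 1 FPKM added to each group), where unchanged groups gave 1412 and 1414. All 15 flavonoid genes in this set were further up in light than in det1-1 (median 2.31) and than in pifq (6.16; 3.95 with 1 FPKM added to each group). Root genes were further up in light than in pifq in 4 of 7 (median 1.43, percentile 99.8). Auxin genes were further down in light, with medians of -1.57 against det1-1 (-0.24 without genes of repeated sequence) and -1.23 against pifq, and PIF-activated genes had medians of -1.33 and -1.45, although 5 of 19 were further up in light than in pifq. Photosystem genes were further down in light than in pifq in 15 of 18 (median -1.47). At the same minimum of 5 FPKM, ELIP1 had the largest difference between light and pifq (12.35), at 1373 and 0.256 FPKM. BGLU24, a beta-glucosidase, had the largest of those further up in light than in det1-1 (6.92), at 55.4 and 0.412 FPKM.

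**Figure D2:**
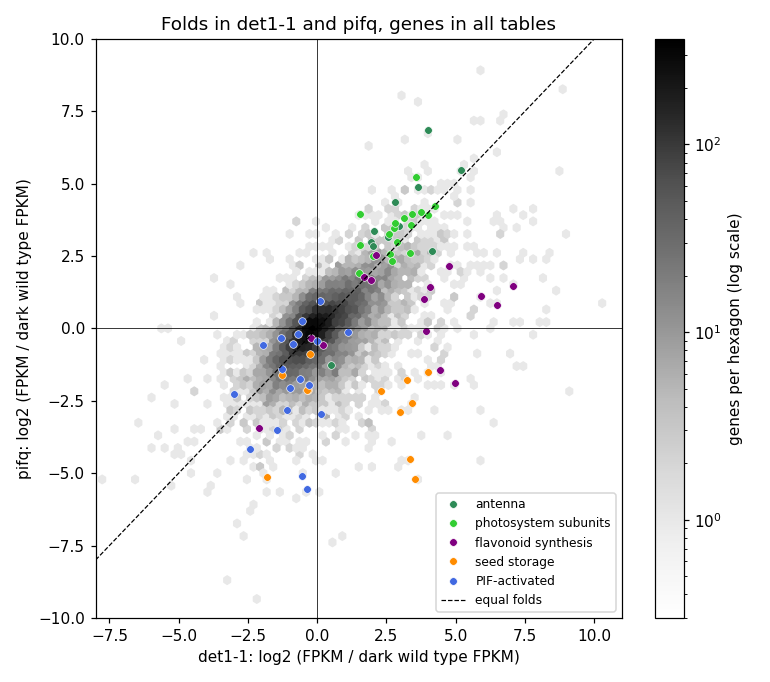
Log2 fold over dark wild type in det1-1 (horizontal axis) and in pifq (vertical axis) for 13820 genes, shaded by number of genes, with members of 5 lists as coloured points and a dashed line where both folds are equal. Pearson r across genes is 0.59; 10 of 15 flavonoid and 10 of 12 seed genes have a fold at least 2 times higher in det1-1, with median differences of 2.65 and 4.76, or 0.85 and 2.57 with 1 FPKM added.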

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

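No explanation was tested for the values in this part, and the check that found them, of entries outside the comparisons, was fixed beforehand. Entries without a gene name were left out of every comparison, and some of them stood above dark wild type by at least 2-fold. In the light table this held for 29 of 185 such entries compared by the authors' program, with 51 at least 2-fold below. In the det1-1 table it held for 56 of 187, with 63 below, and in the pifq table for 22 of 190, with 105 below. Of the entries at least 2-fold above dark wild type, the one with the highest FPKM in the compared group is given, which need not have the largest fold. It went from 1894 FPKM in the dark to 61164 FPKM in light (32.3-fold). In det1-1 it went from 454 to 2859 FPKM (6.29-fold), and in pifq from 51.3 to 198 FPKM (3.86-fold). These entries carry no identifier by which a gene could be named. Whether a library stands apart from the others of its group could not be examined, because each group has a single value.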

How the results depend on the processing

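The alternatives for the tolerance between tables, genes with several entries, repeated sequence, 1.5-fold and 4-fold calls and a minimum of 5 FPKM were chosen after the tables had been seen; the others were set before. No paired analysis was possible because each table carries 1 value per group and no replicate numbers. For the same reason leaving out single libraries, a replicate block, stricter q-values, other adjustments for multiple tests and tests with standard errors were not run. Of counts of genes, 175 stayed within 1.5 times of the reported value over all alternatives and 59 did not. Of folds of named genes, 2240 kept their side of 2-fold and, where they had reached it, their direction. Of those that had reached it, 62 fell under it and 0 changed direction. Of list medians and differences, 1179 were kept, 40 moved and 3 that had reached a log2 of 1 changed sign. Smaller ones were not checked for a change of sign. Kept means inside the bootstrap interval of the reported value and, where either value reached a log2 of 1, within 1.5 times of it; that last limit was set after the values were seen. Pearson r across genes ranged from 0.55 to 0.63 for det1-1 and pifq, from 0.58 to 0.64 for light and det1-1, and from 0.39 to 0.45 for light and pifq. Of the pseudocounts, only that of 1 FPKM was applied to list medians, list differences and r. Whether they hold with 5 FPKM added was therefore not examined. Centring each table on its median moved the share of higher among called genes from 55.1% to 54.1% in light, from 64.0% to 66.9% in det1-1 and from 49.5% to 49.4% in pifq. The unknown depth limits all low values, and no count here has an error.

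Without a minimum level, 2198 genes were lower in det1-1 (1441 with it) and 1496 were further down in det1-1 than in pifq (927); by construction these additions are genes under 1 FPKM. With at least 5 FPKM, the latter count was 557.

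A pseudocount shrinks folds of low genes by construction. With 1 FPKM, 1132 genes were further down in light than in pifq (1702 without) and 457 in det1-1 than in pifq (927). With reported values in brackets, medians in light were then 4.098 (6.48) for flavonoid and 1.402 (3.05) for stomatal genes. In det1-1 they were 1.08 (3.86) for flavonoid, 1.31 (2.304) for seed, 0.62 (1.26) for heat stress and 1.29 (3.11) for stomatal genes, and in pifq -1.43 (-2.13) for seed, -1.39 (-5.47) for heat stress, -1.78 (-2.85) for defence and 1.84 (3.84) for stomatal genes. Median differences between light and det1-1 were -1.66 (-2.92) for seed and -1.0001 (-2.89) for defence genes, and between light and pifq 3.95 (6.16) for flavonoid, 0.72 (1.82) for seed and 2.02 (5.74) for heat stress genes. Between det1-1 and pifq they were 0.85 (2.65) for flavonoid, 2.57 (4.76) for seed, 1.78 (4.62) for heat stress and -1.29 (-1.59) for stomatal genes.

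Other fold limits also change counts by construction. For 5 FPKM added, at least 1.5-fold, and at least 4-fold in turn, the counts were as follows. Higher in light were 918, 3210 and 608 genes, and lower 694, 2902 and 389. Higher in det1-1 were 1333, 3853 and 1004, and lower 543, 3143 and 256. Higher in pifq were 792, 3520 and 567, and lower 955, 3456 and 537. Light and det1-1 shared 472, 1856 and 320 higher and 236, 1319 and 92 lower genes. Light and pifq shared 302, 1407 and 197 higher and 283, 1283 and 121 lower. The mutants det1-1 and pifq shared 498, 1931 and 332 higher and 347, 1715 and 114 lower. Further up in light than in det1-1 were 491, 2506 and 254, and further down 823, 3228 and 523. Further up in light than in pifq were 981, 3250 and 728, and further down 555, 3239 and 391. Further up in det1-1 than in pifq were 836, 3160 and 673, and further down 160, 2265 and 134.

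Of the medians that had reached a log2 of 1 and changed sign, that of the PIF family in pifq was 0.029 without the tolerance between tables (-1.98 with it), because PIF4 and PIF8 then enter. With only genes of few repeated stretches, the cell wall median in light was 0.026 (-1.23) and the defence and jasmonate difference between light and pifq was -1.89 (1.00); fewer members were left, and the cause was not tested further. The same restriction gave medians of -1.20 (-2.46) for auxin genes in light, and of 4.26 (0.35) for defence and 0.97 (2.304) for seed genes in det1-1. Differences were -1.499 (-0.70) for the PIF family, -0.24 (-1.57) for auxin and -6.46 (-2.89) for defence genes between light and det1-1, and 2.08 (0.95) for the PIF family between light and pifq.

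Without a minimum level, medians were -0.20 (-1.31) for mitochondrial genes in det1-1, and -0.59 (-2.85) for defence and -1.24 (-5.47) for heat stress genes in pifq. Without the tolerance between tables they were -0.60 (-1.23) for cell wall and -1.18 (-0.64) for plastid-encoded genes in light, 1.67 (0.026) for the PIF family in det1-1 and -1.06 (-2.85) for defence genes in pifq; with a tolerance of 1.1-fold the cell wall median in light was -0.60 (-1.23). The defence median in det1-1 was 4.26 (0.35) with at least 5 FPKM and 4.26 with the entries of a gene summed. The heat stress difference between light and det1-1 (1.29) was 0.84 without a minimum level, 0.86 without the tolerance, 0.77 at 1.1-fold and 0.24 with at least 5 FPKM.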

Other observations

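The tests of table scaling and of low levels on flavonoid genes and of less seed RNA in pifq, the family groups, the further seed list and the patterns themselves were chosen only after the results were seen; the other tests were set before their results. Families were also taken by product name, some members of which are in the fixed lists. SAUR-like genes were lower in 31 of 60 in light (median log2 fold -1.28, percentile 0), in 17 of 60 in det1-1 (-0.47, percentile 0.02) and in 34 of 61 in pifq (-1.20, percentile 0). Genes with names of ribosomal proteins were higher in 7 of 71 in light (0.21, percentile 98.1), 26 of 71 in det1-1 (0.84, percentile 100) and 18 of 68 in pifq (0.55, percentile 99.99). Pentatricopeptide repeat proteins, which process organelle RNA, were higher in 29 of 126, 49 of 136 and 31 of 122 (medians 0.47, 0.68 and 0.63, each at percentile 100). Thioredoxins had medians of 0.32, 0.72 and 0.47 for light, det1-1 and pifq in turn, with 21 of 68, 30 of 70 and 27 of 68 higher.

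Differences between the comparisons were not tested for these families. In the same order, heat shock proteins had medians of 1.07, 0.39 and 0.074, with 20, 12 and 6 genes higher and 2, 1 and 8 lower. B-box factors had medians of 0.63, 0.37 and -0.48, and glutathione S-transferases of 0.62, -0.044 and -0.063. Class III peroxidases, which act in the cell wall, had medians of 0.10, -0.28 and -0.56, and aquaporins, which pass water through membranes, of -0.59, -0.43 and -0.94. Cytochrome P450 enzymes had medians of -0.25, -0.33 and -0.44, WRKY factors of -0.15, -0.30 and -0.26, and proteasome subunits of 0.34, 0.44 and 0.21. Expansins had medians of -0.033, -0.45 and -0.15, UDP-glycosyltransferases of 0.0042, -0.010 and 0.075, histones of -0.13, -0.021 and -0.084, and tubulins of -0.45, -0.12 and 0.37. Single genes of note, chosen after their values were seen, were LFY, a floral meristem regulator, from 0.107 to 9.25 FPKM in det1-1, and QQS from 0.780 to 70.7 FPKM in pifq.

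The same dark wild type libraries gave different values in different tables. Scaled values were over 1.5-fold higher in the light table than in the det1-1 table for 347 genes and lower for 2, and 304 were at 0 in 1 of them. The genes higher in the light table, with those at 0 in the det1-1 table, had a median of 79.1% of their 32-base stretches repeated elsewhere in the genome (575 genes, bootstrap 95% interval 69.5 to 86.1), against 0% for 16047 others. This is what different handling of reads shared between gene copies would give, so it may be the source of these differences, and levels of multi-copy genes are the less certain for it. Genes that differed between the light and pifq tables overlapped another gene 1.096 times as often as others (interval 1.02 to 1.18), which argues against joined overlapping genes as the main source there. Adjacent genes joined without an annotated overlap are not seen by this count, so joined neighbours stay open. The median share of repeated stretches of these differing genes was 0% (mean 6.24%, against 3.39% for the others). The explanation by gene copies is therefore given for the light and det1-1 tables only. No biological explanation applies to the same libraries.

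Flavonoid genes were further up in det1-1 than in pifq, with a median log2 difference of 2.65. Some members reached 1 FPKM only in det1-1 or light, so the minimum level leans this median upward. With 1 FPKM added to each group it was 0.85 (interval 0.29 to 2.43), with 7 of 15 at least 2-fold further up and 0 further down, so large ratios of genes near 0 FPKM may account for the size of the median. Removing a trend on GC content and length left 2.71, which argues against it as the whole cause, and the median difference over all genes was 0.018 (interval 0.0040 to 0.032), which argues against the scaling of the tables, since it shifts every gene alike. The 13 members with few repeated stretches had a median difference of 2.65 (interval 0.80 to 5.61), with 9 at least 2-fold further up and 0 further down, which argues against reads shared between copies. The unknown spread between libraries and a biological difference between the genotypes stay open.

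Of the seed maturation and storage genes, 7 of 13 were higher and 2 lower in det1-1 (median 2.304, interval -0.32 to 3.33; 1.31 with 1 FPKM added to both groups), and 9 of 10 were lower in pifq (-2.13). A further list of 17 late embryo and oil body genes, 14 of which were analysed in det1-1, had a median of -0.0062 in det1-1 (interval -0.43 to 0.50), with 2 higher and 3 lower. This argues against seed RNA carried over evenly across seed genes. The list holds no cruciferin or albumin gene, so it cannot test whether storage transcripts alone were carried over. EM1 and EM6 of the first list were not higher in det1-1 either (log2 -0.32 and -0.35). Removing a GC and length trend from the first list left a median of 2.14. Its members with few repeated stretches had a median of 0.97, so reads shared between copies stay open. OLEO3, an oil body protein, was lower in each table, from 91.0 to 8.65 FPKM in light, 84.4 to 3.51 FPKM in det1-1 and 88.5 to 2.58 FPKM in pifq. In pifq the further list had a median of -2.09 (12 genes, all at least 2-fold lower, interval -3.23 to -1.72), so less seed RNA in pifq may account for the lower values, and a difference in the seed programme between genotypes was not tested and stays open. In light the further list had a median of -0.25 (13 genes, 2 higher and 2 lower).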
